A study of Mus musculus with 30 samples.

How the data were processed

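Bulk mRNA sequencing of GFP-positive cells sorted from mouse lung adenocarcinomas was analysed in 30 libraries of 6 groups, each library from 1 mouse. Per the labels' protocols, cDNA was made from 2 ng of RNA (RIN 9.0 to 9.7) with the SMART-Seq v4 kit and 12 PCR cycles. Libraries were made with the KAPA Hyper kit and 8 PCR cycles and sequenced as paired reads of 100 bases on an Illumina NovaSeq instrument. These kits do not mark the strand, so overlapping and antisense genes cannot be told apart, and neither can near-identical copies.

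The authors deposited 1 table of counts per gene symbol and library, with no normalization. Reads were aligned with STAR 2.7.5a and counted with HTSeq 0.13.5, against GRCm38, per the submitters' notes. The counting mode and annotation release are not given. A further deposited table gives reads in the categories that name no gene, which were left out of library sizes and tests. Of all counts in a library, 69.38 to 78.62% lay in genes (median 75.95%), 14.17 to 23.24% were not aligned, 2.02 to 4.35% had no feature, 1.06 to 1.66% were ambiguous and 2.50 to 3.38% were not unique. Counts in genes ran from 22347726 to 29627304 per library. The 10 most abundant genes of a library took 16.56 to 30.81% of them, and TMM factors ran from 0.869 to 1.152. No replicate pair agreed within sampling noise (lowest chi-square per degree of freedom 17.9 over 69 pairs), so each library counted as 1 replicate. Age and guide came from the labels, and sex from the deposited library table. Replicates were numbered in accession order and pair nothing.

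All counts were tested with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood F test, TMM normalization, filterByExpr, Benjamini-Hochberg adjusted p under 0.05) in 1 fit of the 6 groups with 24 residual degrees of freedom. Of 31017 gene symbols, 5906 were at 0 in all libraries and 15230 were tested. An adjusted p of a gene in the text is from this edgeR fit, and log2 fold changes are its estimates with their standard errors. CPM values are TMM-scaled, with a prior count of 1 on the log2 scale. The contrasts were age in controls, targeting in young and in aged mice with both guides weighted equally, their difference, age in targeted mice, the guides against each other and each guide against the controls of its age. The contrast of the guides in young mice was added after the data were examined. Nupr1 was also tested with two-sided exact permutation tests on log2 CPM. Gene lists, 36 in all, covered tumour cell states, stress and metabolic pathways, iron handling and markers of other cell types that a sort could carry over. They were tested with camera of limma 3.58.1 (inter-gene correlation preset to 0.01, adjusted over lists within a contrast). Camera with an estimated correlation and fry served as alternatives, and members were counted over all genes and adjusted over the list alone. A list's adjusted p is camera's unless stated. The medians of all genes' log2 fold changes lay between -0.04 and 0.03.

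Lists, contrasts, tests, the alternatives named next and the rule for named genes were fixed before the data were examined. The rule names Nupr1, a panel of 14 genes, and in the age contrast of controls and both targeting contrasts up to 10 rises and 10 falls with the largest log2 fold change among called genes with a mean log2 CPM of at least 2 and, for targeting, 1 sign for both guides. With fewer than 3 in a direction, the 3 with the smallest p stand in. It adds up to 4 members with the smallest p of each called list, and 5 per direction in the interaction and guide contrasts. Predicted genes, pseudogenes, mitochondrial and immunoglobulin segments and sex-linked markers were left out of the ranked parts. Symbols were placed on GENCODE M21 (GRCm38), which held 98.44% of the table's symbols and all 214 named genes.

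The alternatives were DESeq2's size factors or upper quartile normalization, no filter and a stricter filter (CPM of at least 1 in 10 libraries), DESeq2 1.42.0, limma voom with sample quality weights, the groups of a contrast alone, Xist as a covariate, mice of ID prefix AS or AH alone, a 2-fold or a 0.1 threshold, and leaving out each library. Added after the data were seen were sex or the percent of counts not aligned as a covariate, female mice alone, leaving out the 3 libraries whose macrophage or ciliated marker mean was above 4 log2 CPM, these together with sex, and offsets per library for GC content and transcript length (splines with 4 degrees of freedom, known for 99.09% of tested genes). Correlations between contrasts with shared controls were set beside 20 simulations of unchanged groups, and up to 100 regroupings of the libraries were refitted for each count.

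The fit was tested on simulated counts for the 15230 genes with 200 changed. In the age contrast of controls it recovered 22.4, 56.7 and 97% of genes changed 1.5-, 2- and 4-fold. For targeting in young mice it recovered 55.2, 92.5 and 98.5%, and in aged mice 17.9, 56.7 and 98.5%. False calls made up 3.31, 6.29 and 8% of calls. Regrouping the real controls gave up to 825 genes, so these rates may be too favourable. Changes under 2-fold were thus often not detectable with 3 aged control libraries.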

Results

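Lung adenocarcinomas were compared between aged and young mice, with and without targeting of Nupr1, a small stress-induced nuclear protein. The mice carried a Cre-activated oncogenic Kras allele, floxed Trp53 and a Cre-activated transgene for EGFP and Cas9. A lentivirus brought Cre into the lung together with a control single guide RNA (sgControl) or with 1 of 2 guides against Nupr1 (sgNupr1.1 and sgNupr1.2). Mice were over 2 years old (aged) or 12 to 16 weeks old (young) at induction, and GFP-positive cells were sorted from the tumours 10 weeks later. The 30 libraries were 7 young sgControl, 6 young sgNupr1.1, 7 young sgNupr1.2, 3 aged sgControl, 4 aged sgNupr1.1 and 3 aged sgNupr1.2. Counts assigned to genes ranged from 22347726 to 29627304 per library. By group they spanned 23.8 to 29.63 M in young sgControl, 22.35 to 28.68 M in young sgNupr1.1, 22.55 to 27.79 M in young sgNupr1.2, 26.24 to 26.8 M in aged sgControl, 23.75 to 26.97 M in aged sgNupr1.1 and 24.89 to 26.09 M in aged sgNupr1.2. Sftpc, the surfactant protein of alveolar type 2 cells, took 8.02 to 18.3% of the counts. All 3 aged sgControl mice were female, against 2 of 7 young sgControl mice, 3 of 13 young targeted mice and 4 of 7 aged targeted mice. Mouse ID prefixes did not overlap between the ages: young mice had AS, AT or AU and aged mice AH or AF, so prefix and age cannot be told apart.

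Nupr1 mRNA was measured first to check the guide labels. It averaged 335 ± 107 CPM (SD, n = 7) in young sgControl tumours and 308 ± 66.1 CPM (n = 3) in aged sgControl tumours. In young mice it was 125 ± 44.8 CPM (n = 6) with sgNupr1.1 and 186 ± 60.4 CPM (n = 7) with sgNupr1.2, and in aged mice 94.6 ± 9.93 CPM (n = 4) and 71.3 ± 5.42 CPM (n = 3). Nupr1 lies on chromosome 7 of GRCm38, from 126623249 to 126630861 on the minus strand. With both guides weighted equally, targeting lowered it in young mice by a log2 fold change of -1.14 (SE 0.18, adjusted p = 0.00848, two-sided exact permutation p = 0.000232), a change of -54.5%. In aged mice the log2 fold change was -1.91 (SE 0.25, adjusted p = 5.24e-04, exact p = 0.00833, the smallest that 120 regroupings allow), a change of -73.3%. Each guide lowered it in each age, with log2 fold changes of -1.42 and -0.85 in young mice (adjusted p = 0.00891 and 0.0283) and -1.70 and -2.11 in aged mice (adjusted p = 0.0318 and 0.00877). Young targeted libraries ran from 79.5 to 279.9 CPM, and sgNupr1.2 replicates 5 (279.9) and 7 (247) lay within the range of the young controls. The drop did not differ detectably between the ages (difference -0.77, SE 0.32, adjusted p = 0.226). Nupr1 did not differ detectably with age in control tumours (log2 fold change -0.12, SE 0.27, adjusted p = 0.921, exact p = 0.767), and its sign there turned to 0.02 without aged sgControl replicate 3 and to 0.05 without young sgControl replicate 5. Without young sgControl replicate 5 the young targeting difference was -0.97 and no longer passed the threshold. Among targeted tumours, Nupr1 was lower in aged than in young mice (log2 fold change -0.89, SE 0.19, adjusted p = 0.00571, exact p = 0.00185).

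**Figure D1:**
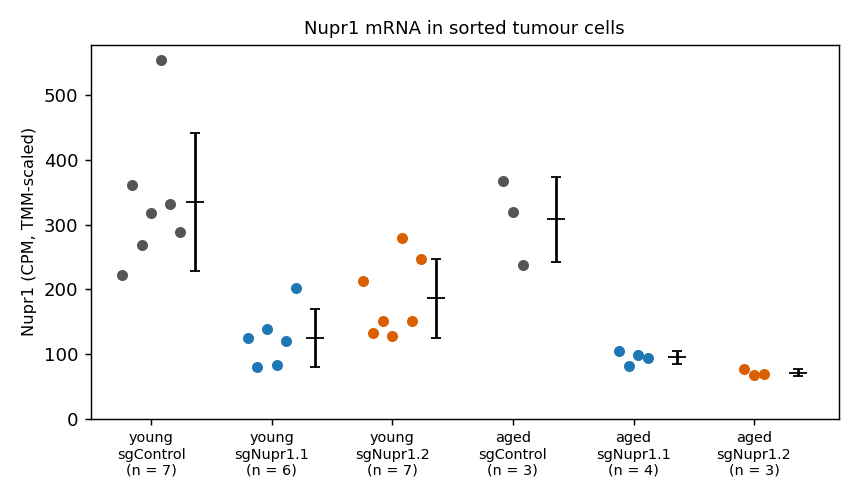
Nupr1 in TMM-scaled CPM (y axis) for each library (points) in the 6 groups (x axis, with n), with the mean and SD of each group as a dash and bars beside the points. Control libraries span 223 to 554 CPM in young and 237 to 368 CPM in aged mice, while young targeted libraries (79.5 to 279.9 CPM) overlap the controls and aged ones lie between 66.9 and 105 CPM.

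First, aged and young control tumours were compared. Genes of cholesterol synthesis were higher in aged tumours, alveolar type 1 (AT1) markers were lower, and 1 aged library carried a strong airway cell signature. Of 24 measured cholesterol synthesis genes all had a positive log2 fold change (median 0.57), and 6 rose by the test over all genes (13 adjusted over the list alone). Sqle, the squalene epoxidase, rose from 52.0 ± 6.06 CPM (SD, n = 7) to 128 ± 62.1 CPM (n = 3; log2 fold change 1.30, SE 0.21, adjusted p = 0.00311). It lies on chromosome 15, from 59315077 to 59331192 on the plus strand. The list mean was 4.82 ± 0.10 log2 CPM in young control and 5.51 ± 0.11 in aged control libraries, with no overlap between the libraries of these groups. Msmo1, Idi1 and Fdps, enzymes of the same pathway, rose by log2 fold changes of 0.79, 1.05 and 0.85 (adjusted p = 0.007, 0.00971 and 0.0347). The calls of these 4 genes ended without aged sgControl replicate 1, where Sqle was at 0.84 (adjusted p = 0.25), and that of Fdps in 9 of 30 single omissions.

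**Figure D2:**
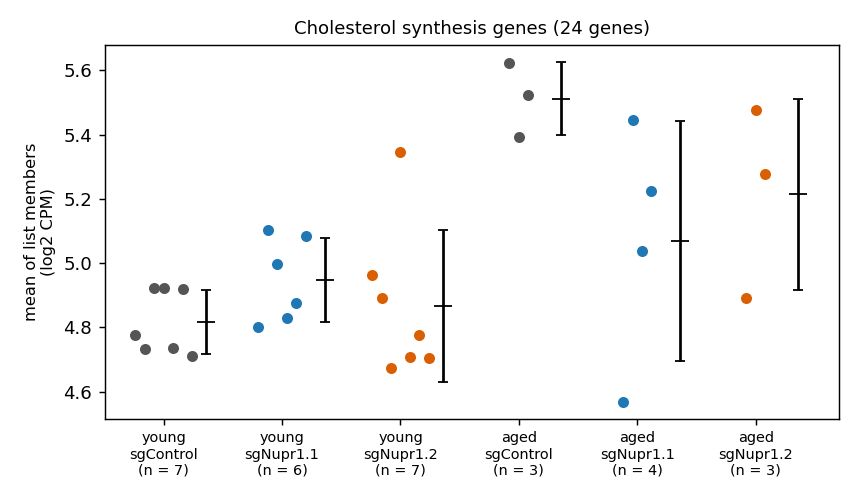
Mean log2 CPM of the 24 cholesterol synthesis genes (y axis) for each library (points) in the 6 groups (x axis, with n), with group mean and SD as a dash and bars. The 3 aged control libraries lie between 5.39 and 5.62, above the 7 young control libraries at 4.71 to 4.92, while the aged targeted libraries spread from 4.57 to 5.48.

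The 18 AT1 markers had a median log2 fold change of -0.59 with age. Akap5 (-1.30, SE 0.35, adjusted p = 0.0265) and Emp2 (-0.55, SE 0.16, adjusted p = 0.0401) fell, and adjusted over the list alone 7 members were lower and 1 higher. The cholesterol list and the AT1 list passed the competitive gene set test (adjusted p = 7.02e-17 and 1.99e-09) and again with an estimated correlation (adjusted p = 0.0477 and 0.034). The other 10 lists past the threshold did not pass with it. Genes of the high-plasticity tumour cell state had a median of -0.60 (adjusted p = 1.02e-08; adjusted p = 0.33 with an estimated correlation) with none of 25 past the gene threshold (3 adjusted over the list alone), among them Slc4a11 at -1.66 (SE 0.51, adjusted p = 0.0632) and the keratin Krt8 at -0.62 (SE 0.21, adjusted p = 0.096). The senescence and secretory list was lower (median -0.50, adjusted p = 1.13e-04; adjusted p = 0.285 with an estimated correlation), and of its 24 members the protease inhibitor Timp2 (-0.57, SE 0.15) and Igfbp7 (-0.92, SE 0.26) fell (adjusted over the list alone, 5 lower and 1 higher). Ribosomal protein genes had a median of -0.30 (adjusted p = 6.31e-09; adjusted p = 0.63 with an estimated correlation) and none of 31 passed by itself or adjusted over the list alone, with Rps18 at -0.58 (SE 0.24, adjusted p = 0.235). Smaller shifts were a lower ATF4 target list (median -0.20, adjusted p = 0.00766), mesenchymal list (-0.53, adjusted p = 0.0289), cell cycle list (-0.27, adjusted p = 0.0295) and macrophage list (-1.08, adjusted p = 0.0295), with no member called either way. With an estimated correlation their adjusted p were 0.63, 0.63, 0.883 and 0.835. The unfolded protein response list was higher (median 0.14, adjusted p = 0.00996; adjusted p = 0.63 with an estimated correlation), and 1 of 20 members, the chaperone Hyou1, rose (1.01, SE 0.29, adjusted p = 0.0461; also 1 adjusted over the list alone). Of 30 single omissions 23 ended the call of Hyou1, 3 that of Akap5, 7 that of Emp2, 4 that of Timp2 and 6 that of Igfbp7. Without aged sgControl replicate 1 the ATF4, ribosomal and macrophage lists were at adjusted p = 0.372, 0.161 and 0.243, and the cell cycle list turned higher (0.967). Without replicate 2 the mesenchymal and unfolded protein lists were at 0.127 and 0.267, and Krt8 and Rps18 passed (adjusted p = 0.0312 and 0.0346). Without replicate 3 the mesenchymal, ATF4, unfolded protein, cell cycle and macrophage lists were at 0.0806, 0.102, 0.311, 0.495 and 0.102. Among young controls the mesenchymal call ended without replicate 5 (0.132), the cell cycle call without replicates 1, 2, 6 or 7 (0.129 to 0.211) and the macrophage call without replicates 4, 5 or 6 (0.0567 to 0.212).

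In all, 583 genes were higher and 51 lower in aged than in young control tumours, with 2104 at an unadjusted p under 0.05. The largest rises were in genes of motile cilia. All 13 ciliated cell markers rose (median log2 fold change 4.79; list adjusted p = 1.99e-09, but adjusted p = 0.33 with an estimated correlation; 13 adjusted over the list alone), and so did 3 of 12 club cell markers (median 1.70; adjusted p = 2.17e-04, and adjusted p = 0.351 with an estimated correlation; 4 adjusted over the list alone). Cyp2a5 (7.86, SE 1.55, adjusted p = 0.0058), which has a near-identical copy in Cyp2a4, and the cilium genes Rsph4a (6.54, SE 1.43, adjusted p = 0.00862), Cfap65 (6.42), Cdhr4 (6.37), Spag6l (6.19), Cfap206 (5.99), Cfap44 (5.93), Cdhr3 (5.92), Ak7 (5.82) and Ccdc40 (5.76) led, and Scgb1a1, the club cell secretoglobin, rose by 4.72 (SE 0.91, adjusted p = 0.00538). The ciliated marker mean was 5.98 log2 CPM in aged sgControl replicate 1, against -0.42 and -0.45 in the other 2 aged controls, and without replicate 1 the list's median log2 fold change was -0.14 (adjusted p = 0.819, and 0.400 for the club list). Without it Rsph4a, Cfap65, Cdhr4, Spag6l, Cfap206, Cfap44, Cdhr3 and Ak7 turned negative (-1.39, -1.03, -2.50, -0.64, -2.915, -0.20, -0.83 and -1.54). There Cyp2a5, Ccdc40 and Scgb1a1 were at 0.34, 1.27 and 1.11. The largest falls were in Sema3a, a secreted guidance cue (-2.74, SE 0.42, adjusted p = 0.00311, from 20.5 ± 7.04 to 3.06 ± 1.93 CPM; chromosome 5, from 13125414 to 13602565, plus strand), the peptide transporter Slc15a1 (-2.61, SE 0.57, adjusted p = 0.00866), Zmat4 (-2.16), Lgals1 (-1.79), Cdh13 (-1.77), Aldh1a3 (-1.74), Pdgfb (-1.71), Tgfb2 (-1.65), Fbln5 (-1.54) and Rps3a1 (-1.49). The calls of Zmat4, Cdh13, Fbln5, Lgals1 and Aldh1a3 ended in 8, 6, 4, 3 and 3 of 30 single omissions. Sema3a, Cdh13, Cdhr4, Spag6l and Rps3a1 overlap other annotated genes or pseudogenes, which unstranded counts cannot separate. Without aged sgControl replicate 1, edgeR called 0 genes (1016 at an unadjusted p under 0.05), and without replicate 2 it called 961. DESeq2 called 530 genes (437 shared) and limma voom 5. With sex as a covariate edgeR called 100 (98 shared), and among female mice alone 0 (632 at an unadjusted p under 0.05).

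**Figure D3:**
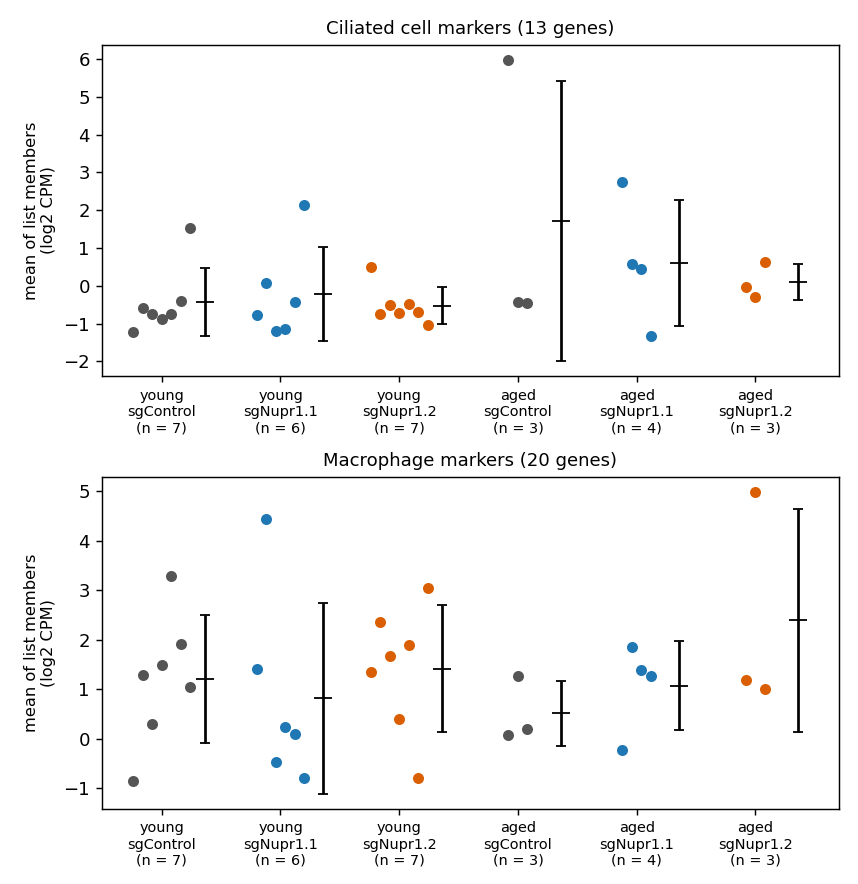
Mean log2 CPM of the 13 ciliated cell markers (top) and the 20 macrophage markers (bottom) for each library (points) in the 6 groups (x axis, with n), with group mean and SD as a dash and bars. One aged control library stands at 5.98 for ciliated markers, and the highest macrophage means are 4.98 in an aged sgNupr1.2 and 4.43 in a young sgNupr1.1 library.

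In young mice, Nupr1 was the 1 gene that differed between targeted and control tumours (edgeR, with 1315 genes at an unadjusted p under 0.05; DESeq2 called 21 and limma voom 3). The genes next in rank did not pass. They were Clmn (log2 fold change 0.63, SE 0.13, adjusted p = 0.103), Csnk2a2 (0.98, SE 0.20, adjusted p = 0.103), Tceal8 (0.58, SE 0.12, adjusted p = 0.147), Pld1 (-0.72, SE 0.15, adjusted p = 0.103) and Glis3 (-0.92, SE 0.21, adjusted p = 0.23). As groups, all 31 ribosomal protein genes had positive values (median 0.22, adjusted p = 7.5e-06), as did 27 of 31 nuclear respiratory chain genes (median 0.18, adjusted p = 0.0029), and the NF-kappaB and acute-phase list was lower (median -0.20, adjusted p = 0.00798). No member of these 3 lists passed over all genes or adjusted over the list alone, and each list had adjusted p = 0.977 with an estimated correlation. The percent of counts not aligned was 15.94 to 23.24 in young targeted and 16.39 to 18.20 in young control libraries. With it as a covariate the ribosomal list was at adjusted p = 0.862 and the respiratory chain list turned lower (adjusted p = 0.821). The respiratory chain call ended without young sgNupr1.2 replicate 1 (adjusted p = 0.0584), and the NF-kappaB call without young sgControl replicate 5 (adjusted p = 0.08997), whose NF-kappaB and macrophage means, 4.94 and 3.295 log2 CPM, were the highest of the young controls. Rps19 was at 0.29, Rpl13 at 0.29, Uqcrfs1 at 0.18 and Cycs at 0.25 (adjusted p = 0.573 to 0.576), while the chemokine Cxcl5 was at -1.20 (SE 0.42, adjusted p = 0.548) and Birc3 at -0.29 (SE 0.11, adjusted p = 0.548). Sftpc (0.29, adjusted p = 0.576) and Ftl1 (0.33, adjusted p = 0.538) did not pass either. Without young sgControl replicate 5, edgeR called 0 genes (1042 at an unadjusted p under 0.05).

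In aged mice, targeted tumours had 35 genes higher and 245 lower than control tumours (2465 at an unadjusted p under 0.05). Sema3a, low in aged controls, rose to 16.2 ± 2.33 CPM (n = 7; log2 fold change 2.41, SE 0.41, adjusted p = 0.0106). Further rises were in the receptor tyrosine kinase Axl (3.39, SE 0.91, adjusted p = 0.0493), Slc15a1 (2.33, SE 0.57, adjusted p = 0.0324), Cers6 (1.83), Galnt10 (1.78), Igsf9 (1.47), Tspan5 (1.44), Asap1 (1.39), Kcnn3 (1.37) and Itih2 (1.36). The largest falls were in AU040972 (-5.12, SE 1.23, adjusted p = 0.03), the immunoglobulin receptor Pigr (-4.48, SE 0.97, adjusted p = 0.0192), Fgg (-4.22), Mapk15 (-4.17), Ccdc40 (-4.13), Corin (-4.12), Pcp4l1 (-3.99), Retnla (-3.83), Wnt11 (-3.80) and Foxj1, a master regulator of ciliogenesis (-3.79, SE 0.91, adjusted p = 0.0297). Sema3a, Cers6, Galnt10, Asap1, AU040972 and Corin overlap other annotated genes. Of 13 ciliated markers (median -3.79) 5 fell (13 adjusted over the list alone), among them Pifo (-2.25), Cfap126 (-3.27) and Dynlrb2 (-2.69). Foxj1 was at 186 CPM in aged sgControl replicate 1, and Foxj1 in aged controls averaged 63.3 ± 106 CPM. Without that library AU040972, Mapk15, Ccdc40, Pcp4l1, Wnt11, Foxj1 and Dynlrb2 turned positive (0.97, 1.17, 0.36, 1.01, 0.54, 1.055 and 0.47), while Cfap126 was at -0.09, Pifo at -0.88 and Fgg at -2.69. The call of each gene named here ended without it, and those of Axl, Tspan5, Ccdc40 and Igsf9 ended in 24, 22, 20 and 19 of 30 single omissions. Axl was at 73.4 ± 135 CPM in aged targeted tumours, and its log2 fold change was 1.77 without aged sgNupr1.2 replicate 2, whose macrophage marker mean was 4.98 log2 CPM. Without aged sgControl replicate 3, the values of Pigr, Corin and Retnla were -2.19, -0.67 and -0.79.

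By the preset test 15 gene groups differed in aged mice, and none did with an estimated correlation, where the adjusted p was 0.553 for most, 0.668 for the ATF4 and macrophage lists and 0.701 for the respiratory chain list. With the percent of counts not aligned as a covariate the respiratory chain list turned higher (adjusted p = 0.0197), and the mitochondrially encoded, ATF4, DNA methylation and club lists lost their call (adjusted p = 0.441, 0.224, 0.482 and 0.232). Cell cycle genes were higher (median 0.62, adjusted p = 1.21e-07, 31 of 32 positive), with the mitotic kinesin Kif23 at 0.85 (SE 0.29, adjusted p = 0.121) and the replication factor Mcm2 at 0.75 (SE 0.28, adjusted p = 0.158). High-plasticity genes were higher (0.40, adjusted p = 7.83e-07, 24 of 25 positive), with Plaur at 1.28 (SE 0.38, adjusted p = 0.0716) and Ndrg1 at 1.27 (SE 0.41, adjusted p = 0.0997). Mitochondrially encoded genes were lower (-0.59, adjusted p = 1.58e-05, none of 11 positive), with mt-Nd2 and mt-Nd4 both at -0.81 (adjusted p = 0.0941 and 0.0997). None of the members of these 3 lists passed over all genes, and adjusted over the list alone 0, 0 and 4 did. Type 2 cell genes (median -0.23, adjusted p = 8.82e-04), cholesterol synthesis genes (-0.28, adjusted p = 8.82e-04) and respiratory chain genes (-0.14, adjusted p = 0.00189) were lower, with Sftpd at -0.64 (SE 0.19, adjusted p = 0.0692) and Acat2 at -0.89 (SE 0.25, adjusted p = 0.0611). Of their members 0 passed over all genes, and 5, 1 and 0 adjusted over the list alone. AT1 markers (0.36, adjusted p = 8.82e-04), senescence genes (0.44, adjusted p = 9.86e-04), ATF4 targets (0.21, adjusted p = 0.0332) and DNA methylation enzymes (0.34, adjusted p = 0.0187) were higher with no member passing either way, including Krt7 at 0.85 (SE 0.27, adjusted p = 0.0856) and Timp2 at 0.43 (SE 0.15, adjusted p = 0.132). The mesenchymal list (0.23, adjusted p = 0.0436) held Axl as its 1 called member (1 higher and 1 lower adjusted over the list alone). The gastric and gut list was higher (median 0.91, adjusted p = 0.0271), although its 1 called member, Pigr, fell (4 higher and 3 lower adjusted over the list alone). Macrophage markers were higher (2.41, adjusted p = 0.00562), with Mrc1 at 2.83 (SE 1.23, adjusted p = 0.246) and Csf1r at 2.58 (SE 1.14, adjusted p = 0.252). Club markers (-1.94, adjusted p = 0.0179, 8 lower adjusted over the list alone) and ciliated markers (adjusted p = 8.73e-06) were lower. None of the macrophage or club members passed over all genes. Without aged sgNupr1.2 replicate 2 the macrophage, mesenchymal and club lists were at adjusted p = 0.218, 0.117 and 0.0787, with Mrc1 at 0.77 and Csf1r at 1.01. Without aged sgControl replicate 1 the ATF4, mesenchymal, gastric, DNA methylation and macrophage lists were at 0.694, 0.0639, 0.0650, 0.0650 and 0.0695, and the club and ciliated lists turned higher (0.830 and 0.254). Without replicate 2 the respiratory chain, type 2 cell, mesenchymal and gastric lists were at 0.891, 0.0667, 0.176 and 0.106, and Kif23, Plaur, Krt7 and Acat2 passed. Without replicate 3 the type 2 cell, AT1, mesenchymal, gastric, ATF4, respiratory chain and DNA methylation lists were at 0.322, 0.0598, 0.0914, 0.185, 0.185, 0.0945 and 0.106. The mesenchymal, gastric and ATF4 calls ended without aged sgNupr1.1 replicate 3 (0.0876, 0.0659 and 0.157), the gastric call without sgNupr1.2 replicates 1 or 3 (0.0934 and 0.0549), the ATF4 call without the latter (0.08595) and the mesenchymal call without young sgControl replicate 4 (0.0502).

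Among genes linked to NUPR1 and iron, Lcn2, which codes for the siderophore-binding lipocalin 2, averaged 2214 ± 1440 CPM (n = 3) in aged control and 1008 ± 282 CPM (n = 7) in aged targeted tumours (log2 fold change -1.13, SE 0.40, adjusted p = 0.135). The iron exporter gene Slc40a1 was at 32.1 ± 21.3 and 52.4 ± 9.96 CPM (0.70, SE 0.33, adjusted p = 0.29). Neither passed the test, but Slc40a1 did without aged sgControl replicate 2 (1.37, adjusted p = 0.0221), while without replicate 3 Lcn2 was at -0.47 and Slc40a1 at 0.35. The count of 280 genes was 496 with DESeq2, 4 with limma voom, 94 with sex as a covariate and 51 (39 shared) with the percent of counts not aligned as a covariate. It was 3 without aged sgControl replicate 1, 834 without replicate 2 and 505 without replicate 3, and among the aged targeted libraries it moved to 431, 128, 114 and 128 without sgNupr1.1 replicates 1, 2, 3 and 4 and to 28, 62 and 28 without sgNupr1.2 replicates 1, 2 and 3.

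The targeting effect was compared directly between the ages. Sema3a (difference of log2 fold changes 2.59, SE 0.47), Asap1 (1.63, SE 0.30) and Ndc1 (1.19, SE 0.22) had a larger effect in aged mice (adjusted p = 0.0454 each). No gene passed in the other direction (2545 at an unadjusted p under 0.05). Ndc1 averaged 11.3 ± 1.06 CPM in aged control, 23.6 ± 2.78 in aged targeted, 21.2 in young control and 19.7 in young targeted tumours. Young libraries had 21.4 to 30.5 CPM with sgNupr1.1 and 12.8 to 17.9 with sgNupr1.2. With the percent of counts not aligned as a covariate none of the 3 was called (adjusted p = 0.185, 0.15 and 0.19). By list, 15 differences passed the preset test. None did with an estimated correlation, where adjusted p = 0.672 for all but the ribosomal (0.894) and macrophage (0.87) lists. The targeting effect was higher in aged mice for cell cycle genes (median difference 0.72, adjusted p = 2.05e-05), with Kif23 at 0.97 (SE 0.35, adjusted p = 0.173) and Mcm2 at 0.96 (SE 0.33, adjusted p = 0.165). It was also higher for high-plasticity genes (0.49, adjusted p = 2.32e-04), with Itga2 at 1.54 (SE 0.49, adjusted p = 0.132), and AT1 markers (0.37, adjusted p = 0.00322). It was lower for mitochondrially encoded genes (-0.55, adjusted p = 3.51e-05), with mt-Nd4 at -1.18 (SE 0.32, adjusted p = 0.0943), and for respiratory chain genes (-0.32, adjusted p = 3.51e-05). Lower too were cholesterol synthesis genes (-0.44, adjusted p = 2.32e-04), with Acat2 at -1.04 (SE 0.31, adjusted p = 0.117), and type 2 cell genes (-0.23, adjusted p = 0.00606), with S100g at -1.07 (SE 0.27, adjusted p = 0.0806). No list member passed over all genes. Adjusted over the list alone 13 ciliated, 6 mitochondrial, 4 club, 2 cholesterol and 1 type 2 cell genes were lower, and 1 senescence and 1 DNA methylation gene higher. Also called were the senescence (0.55, adjusted p = 0.00735), mesenchymal (0.43, adjusted p = 0.0102), gastric (1.08, adjusted p = 0.0377), DNA methylation (0.43, adjusted p = 0.0212) and macrophage (2.02, adjusted p = 0.0107) lists on the higher side. On the lower side were the ribosomal (-0.29, adjusted p = 0.0176), club (-2.14, adjusted p = 0.0346) and ciliated (-3.76, adjusted p = 8.33e-05) lists. With the percent of counts not aligned as a covariate the ribosomal and respiratory chain lists turned higher (adjusted p = 8.71e-09 and 0.0188), and the mitochondrially encoded, DNA methylation and club lists lost their call (0.774, 0.709 and 0.575). The gastric call ended in 14 of 30 omissions (0.0542 to 0.229), those of aged sgControl replicates 1 to 3, aged sgNupr1.1 replicate 3, aged sgNupr1.2 replicates 1 and 3, young sgNupr1.1 replicates 1 to 3, young sgNupr1.2 replicates 2 and 6 and young sgControl replicates 2, 5 and 7. The club call ended in 8 (0.0527 to 0.942), those of aged sgControl replicate 1, aged sgNupr1.1 replicate 4, aged sgNupr1.2 replicates 1 and 2, young sgNupr1.1 replicate 2, young sgNupr1.2 replicate 5 and young sgControl replicates 1 and 4. The club and ciliated lists turned higher without aged sgControl replicate 1 (0.942 and 0.542), where the senescence, DNA methylation and macrophage lists were at 0.0652, 0.0675 and 0.0931. Without replicate 2 the type 2 cell and respiratory chain lists were at 0.0615 and 0.0746, the ribosomal list turned higher (0.303) and Kif23 passed (1.40, adjusted p = 0.0492). Without replicate 3 the type 2 cell, AT1, high-plasticity, senescence, DNA methylation and macrophage lists were at 0.417, 0.0813, 0.0813, 0.0618, 0.115 and 0.0618. Without aged sgNupr1.2 replicate 2 the macrophage and ribosomal lists were at 0.342 and 0.0657. The ribosomal call ended without young sgNupr1.1 replicate 6 or sgNupr1.2 replicate 5 too (0.0797 and 0.0680), and the macrophage call without young sgControl replicate 5 (0.05965). DESeq2 called 332 genes and limma voom 0 (1441 at an unadjusted p under 0.05), and edgeR called 0 with sex as a covariate (2213). With single libraries left out, edgeR called 0 (2178 to 2711) without aged sgControl replicate 1, aged sgNupr1.1 replicates 2, 3 or 4, aged sgNupr1.2 replicate 3, young sgNupr1.1 replicates 1, 3, 4, 5 or 6, young sgControl replicates 1, 3, 5, 6 or 7, or young sgNupr1.2 replicates 1, 2, 4 or 5. It called 1 without aged sgNupr1.2 replicates 1 or 2, 6 without aged sgNupr1.1 replicate 1, 7 without young sgControl replicate 2, 57 without young sgNupr1.2 replicate 3, and 258 and 264 without aged sgControl replicates 2 and 3.

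Across 15230 genes, the age effect in controls and the targeting effect in aged mice ran in opposite directions (Pearson correlation across genes -0.797, covariance -0.989). Both use the same 3 aged control libraries, and 20 simulated sets of unchanged groups around them gave a mean correlation of -0.704 (-0.730 to -0.679) and a mean covariance of -0.370, a covariance difference of -0.619. Genes called in both comparisons numbered 191, all opposite in sign: 179 were higher with age and lower with targeting, and 12 were lower with age and higher with targeting. Lists of the same sizes from the simulated unchanged groups shared 101 (83 to 127) and 13.2 (9 to 19), so the 12 lay within the range that shared controls give with no effect. Independent lists would share 9.38 and 0.117, values that leave out the shared controls. The 12 included Sema3a and Slc15a1, and the 179 Ccdc40, Pifo, Cfap126 and Dynlrb2. Genes are not independent replicates, and 3 aged controls cannot be split with 2 libraries on each side. The excess may come from the shared controls, in part or in whole. Without aged sgControl replicate 1 edgeR called 0 age genes (1016 at an unadjusted p under 0.05, DESeq2 530 and limma voom 5 with all libraries), so none was called in both. The covariance was -1.59 without aged sgControl replicate 2, -1.50 without replicate 3 and -0.318 with a stricter filter on low counts.

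Among targeted tumours, 923 genes were higher and 1304 lower in aged than in young mice (4631 at an unadjusted p under 0.05). Genes for ribosomal proteins and the respiratory chain were lower in the aged. Of 31 ribosomal protein genes 29 fell (30 adjusted over the list alone; median -0.58, adjusted p = 2.9e-19), led by Rps27, which went from 74.3 ± 24.1 CPM (n = 13) to 38.3 ± 5.02 CPM (n = 7; log2 fold change -0.94, SE 0.16, adjusted p = 0.00228) and Rps19 (-0.76, SE 0.15, adjusted p = 0.00402). Of 31 nuclear respiratory chain genes 19 fell (24 lower and 1 higher adjusted over the list alone; median -0.40, adjusted p = 2.09e-11), including the complex I subunits Ndufs7 (-0.54, SE 0.11, adjusted p = 0.00487) and Ndufa1 (-0.76, SE 0.17, adjusted p = 0.00791), and Cox6c (-0.71, SE 0.16, adjusted p = 0.00849). Of 11 mitochondrially encoded genes 8 fell (9 adjusted over the list alone; median -0.62, adjusted p = 1.57e-05), mt-Nd1 by 0.49 and mt-Nd2 by 0.69 on the log2 scale. Each of these 3 lists had adjusted p = 0.826 with an estimated correlation. The percent of counts not aligned was 14.17 to 16.74 in the aged targeted and 15.94 to 23.24 in the young targeted libraries. The 4 highest ribosomal means, 7.93, 7.575, 7.55 and 7.54, lay in young targeted libraries with 21.59, 18.90, 20.66 and 23.24% not aligned. With this percent as a covariate edgeR called 36 genes (30 shared; 1635 at an unadjusted p under 0.05) in place of 2227. The call of each gene named in this comparison ended, with Rps27 at -0.55 and Ndufs7 at -0.23. The ribosomal list still passed the preset test (adjusted p = 4.56e-04), and the respiratory chain and mitochondrially encoded lists did not (adjusted p = 0.0961 and 0.2215). Many ribosomal protein genes have processed pseudogenes, so their counts are uncertain.

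**Figure D4:**
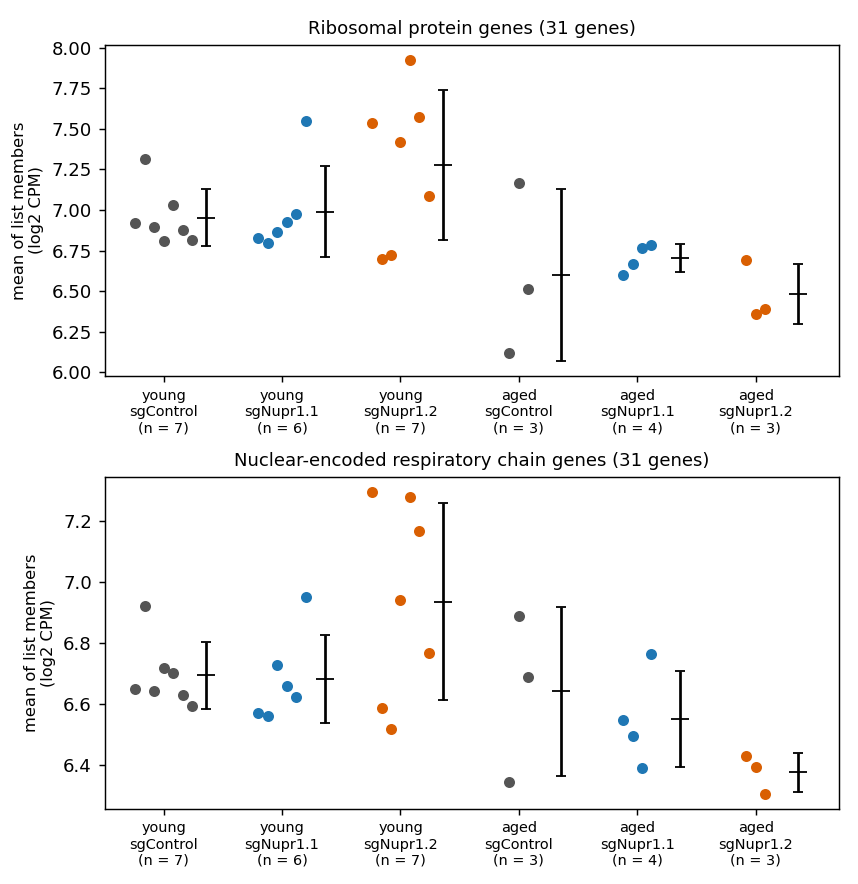
Mean log2 CPM of 31 ribosomal protein genes (top) and 31 nuclear-encoded respiratory chain genes (bottom) for each library (points) in the 6 groups (x axis, with n), with group mean and SD as a dash and bars. Ribosomal protein means lie between 6.36 and 6.78 in the 7 aged targeted libraries and between 6.70 and 7.93 in the 13 young targeted libraries.

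Type 2 cell genes were lower as a group in aged targeted tumours (median -0.17, adjusted p = 0.0282; adjusted p = 0.826 with an estimated correlation, as for the cell cycle, cholesterol and immediate early lists), and 5 of 24 fell (6 adjusted over the list alone), among them S100g (-0.97, SE 0.16, adjusted p = 0.00228), Sfta2 (-0.50) and the surfactant genes Sftpc (-0.66, SE 0.15, adjusted p = 0.0067) and Sftpd (-0.44, SE 0.13, adjusted p = 0.0279). Cell cycle genes were higher (0.44, adjusted p = 9.05e-04), with Kif23 (0.63, SE 0.19, adjusted p = 0.0251), Mcm6 (0.64) and Mcm2 (0.53) rising as 3 of 32 (0 adjusted over the list alone) and the proliferation marker Mki67 at 1.06 (SE 0.40, adjusted p = 0.0717). Cholesterol synthesis genes were higher here too (0.21, adjusted p = 0.0146), with Sqle (0.66, SE 0.14, adjusted p = 0.0066), Hmgcr (0.59), Hsd17b7 (0.60) and Idi1 (0.57) as the 4 of 24 that rose (7 adjusted over the list alone). The immediate early and heat shock list was lower (-0.30, adjusted p = 0.0146), with Klf2 (-0.77, SE 0.23, adjusted p = 0.0276) as the 1 of 24 that fell (0 adjusted over the list alone) and Fos at -0.67 (SE 0.25, adjusted p = 0.0668). That call ended without aged sgNupr1.1 replicate 1 (adjusted p = 0.146), whose list mean was 7.08 log2 CPM against 8.00 to 8.29 in the other aged targeted libraries, and without young sgNupr1.2 replicate 2 (0.052). The type 2 cell call ended without aged sgNupr1.1 replicate 3 (0.134), aged sgNupr1.2 replicate 1 (0.0724), young sgNupr1.1 replicates 3 or 4 (0.0527 and 0.0531) or young sgNupr1.2 replicate 2 (0.0759). The cholesterol call ended without aged sgNupr1.1 replicates 2 or 4 (0.1725 and 0.0725) or aged sgNupr1.2 replicate 2 (0.0876). Of 30 single omissions 17 ended the call of Mcm2, 11 Sfta2, 7 Mcm6, 5 Klf2, 4 Sftpd and 3 each Kif23 and Idi1. Slc40a1 rose by 0.92 (SE 0.21, adjusted p = 0.00794). Offsets for GC content and transcript length moved the share of higher calls from 41.45% of 2227 to 13.9% of 1413, with 902 genes called both ways. The count was 992, 1325 and 1470 without aged sgNupr1.2 replicate 3, aged sgNupr1.2 replicate 2 and aged sgNupr1.1 replicate 3.

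Last, the 2 guides were compared. Averaged over ages, edgeR called 0 genes (944 at an unadjusted p under 0.05; DESeq2 called 7 and limma voom 0). With sgNupr1.1, cell cycle genes were higher than with sgNupr1.2 (median 0.48, adjusted p = 6.64e-14; adjusted p = 0.561 with an estimated correlation), with Mcm2 at 0.57 and Kif23 at 0.48. NF-kappaB and acute-phase genes were lower (-0.48, adjusted p = 5.53e-09; adjusted p = 0.076 with an estimated correlation), with the chemokines Cxcl1 at -0.79 and Cxcl2 at -1.10 and the inhibitor gene Nfkbia at -0.59. Immediate early (-0.29, adjusted p = 2.05e-06), macrophage (-1.34, adjusted p = 6.77e-05), mitochondrially encoded (-0.28, adjusted p = 1.02e-04), autophagy (-0.10, adjusted p = 7.76e-04) and type 2 cell (-0.06, adjusted p = 0.00433) lists were lower. Higher were the fibroblast (0.67, adjusted p = 0.0032), unfolded protein (0.14, adjusted p = 0.0032) and DNA methylation (0.19, adjusted p = 0.00433) lists. Their adjusted p was 0.561 with an estimated correlation, except 0.613 for macrophage, 0.758 for type 2 cell and 0.569 for unfolded protein genes. No member passed over all genes, and adjusted over the list alone 1 DNA methylation gene was higher. Without aged sgNupr1.2 replicate 2, whose macrophage mean was 4.98 log2 CPM, the macrophage, autophagy and fibroblast lists were at adjusted p = 0.787, 0.624 and 0.122, and Cxcl2 was at -0.52. The type 2 cell call ended without aged sgNupr1.1 replicate 3 (0.174) and the unfolded protein call without aged sgNupr1.2 replicate 1 (0.307).

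Against the young controls, sgNupr1.1 gave 1 called gene, Nupr1, while sgNupr1.2 gave 270 higher and 260 lower (425 and 3660 at an unadjusted p under 0.05). In aged mice sgNupr1.1 gave 13 higher and 24 lower and sgNupr1.2 gave 3 higher and 1 lower (2234 and 1936). The guides were also compared directly in young mice, a test added after the data were examined: 156 genes were higher and 176 lower with sgNupr1.1 than with sgNupr1.2. Rbl1 (1.03, SE 0.15, adjusted p = 0.00215), Arhgap19 (1.70), Cbx5 (0.75), Gk (0.46) and Ndc1 (0.77) were higher with sgNupr1.1. Ier5l (-4.00, SE 0.60, adjusted p = 0.00262), Cyhr1 (-1.43), Heca (-1.70), Ppp2cb (-2.05) and Cul3 (-1.94) were higher with sgNupr1.2. All 32 cell cycle genes had positive values (median 0.96, adjusted p = 1.02e-18; adjusted p = 0.527 with an estimated correlation), and 3 passed by themselves (23 adjusted over the list alone). The count was 1110 with DESeq2 and 1627 with limma voom (female mice leave 1 young sgNupr1.1 library and decide nothing). It ran from 103 without young sgNupr1.1 replicate 5 to 1455 without young sgNupr1.1 replicate 6, and with the percent of counts not aligned as a covariate it was 151 (146 shared). For young sgNupr1.2 against control it was 54 (50 shared) with that covariate, and it ran from 136 without young sgControl replicate 3 to 1805 without young sgNupr1.2 replicate 3. Of the young sgNupr1.2 libraries 6 had the ID prefix AT and 1 AS, and all 6 young sgNupr1.1 libraries had AS. With the 2 guides against shared young controls, the correlation of fold changes across genes was 0.335, below the 0.470 of unchanged simulated groups, and with the controls split it had a median of -0.02 (-0.21 to 0.17). In aged mice it was 0.746 against a simulated 0.526, with a covariance of 0.977 against 0.363. The 3 shared controls were not split there, so the excess may come from them. Offsets for GC content and length moved the share of higher calls from 50.9 to 84.1% for young sgNupr1.2, from 47.0 to 11.8% between the young guides, from 35.1 to 46.9% for aged sgNupr1.1 and from 75 to 50% for aged sgNupr1.2.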

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

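The tests of airway cells in 1 aged control library, of the percent of counts not aligned and of the aged targeted tumours against young sgNupr1.1 alone were chosen after the result was seen, as were the contrast of the guides in young mice and the reading of the lone AS library in the test of the ID prefix. Chance marks about 1 in 20 groups of samples as holding a value far from the rest, and 18 of 208 tests did. The groups of 3, aged sgControl and aged sgNupr1.2, were too small to test.

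Single libraries stood apart from their group in single genes, in log2 CPM. Tfrc was at 7.03 in young sgNupr1.1 replicate 6 (others 7.78 to 8.215), Krt8 at 11.7 in young sgControl replicate 5 (10.63 to 11.04) and Mki67 at -0.70 in young sgControl replicate 4 (3.02 to 4.62). List means did so as well. In young sgControl, replicate 4 had cell cycle genes at 1.61 (others 3.485 to 4.61), replicate 2 respiratory chain genes at 6.92 (6.59 to 6.72), and replicate 7 immediate early genes at 6.805 (8.03 to 8.84) and ciliated markers at 1.53 (-1.23 to -0.39). In young sgNupr1.1, replicate 6 had ribosomal protein genes at 7.55 (6.796 to 6.973), and replicate 2 had ferroptosis genes at 5.78 (5.28 to 5.39), neutrophil markers at 3.14 (-2.17 to -0.47) and B cell markers at 2.52 (-2.16 to -0.47). In young sgNupr1.2, replicate 1 had ATF4 targets at 4.87 (5.43 to 5.67), hypoxia genes at 6.21 (5.45 to 5.74), DNA methylation genes at 2.17 (3.01 to 3.46) and ciliated markers at 0.48 (-1.04 to -0.48), and replicate 4 had cholesterol genes at 5.35 (4.67 to 4.96). In aged sgNupr1.1, replicate 1 had NRF2 targets at 6.30 (5.96 to 5.99) and replicate 4 DNA methylation genes at 3.03 (3.75 to 3.82).

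The targeting effect differed between the ages by the test of the difference itself for Asap1 (1.63), Ndc1 (1.19) and Sema3a (2.59). It differed by the preset list test, with median differences of log2 fold changes, for type 2 cell (-0.23), AT1 (0.37), high-plasticity (0.49), mesenchymal (0.43), gastric (1.08), cell cycle (0.72), senescence (0.55), cholesterol (-0.44), respiratory chain (-0.32), mitochondrially encoded (-0.5455), DNA methylation (0.43), ribosomal (-0.29), macrophage (2.02), club (-2.14) and ciliated (-3.76) lists. None of these lists passed with an estimated correlation.

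The libraries were also regrouped at random, 100 groupings per comparison with the real one included. For age in targeted tumours chance is argued against (2227 genes, highest other 1821, 1 of 100 groupings), but ID prefix is not. For age in controls 4 of the 100 groupings, the real one among them, gave at least the real 634 genes (highest other 825). Apart from the real one 27 groupings gave over 100 genes. All of these, and all 4 above, had aged sgControl replicate 1 among the 3 libraries. Groupings with it among the 7 gave 5 genes at most, so the count follows that library. Chance cannot be excluded for the counts of genes in targeting in young mice (1, highest other 5, 8 groupings), targeting in aged mice (280, highest other 601, 7 groupings) and the difference of the effects (3, highest other 345, 11 groupings). The 1 gene in young mice was Nupr1, whose own exact permutation p was 0.000232. For the guides the count was 0 (944 at an unadjusted p under 0.05 with edgeR, DESeq2 7, limma voom 0, highest other 0), which all 100 groupings reach, so nothing follows from them. For targeting in aged mice 18 groupings with other controls gave over 100 genes, all with that library among the controls, and 10 was the highest count with it elsewhere. A grouping with the real controls and the guides redrawn gave 256. For the difference of effects a count of 345 against the real 3 points to a structure of the samples, which was not traced.

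Cilium and airway genes were higher in aged than in young control tumours. Sex imbalance cannot be judged, as the ciliated median log2 fold change among female mice (3.833) includes aged sgControl replicate 1. Airway cells in that library are a candidate source: without it the median went from 4.79 to -0.141 and 0 of 13 markers were called by edgeR. That library held Scgb1a1 at 4218 CPM and Foxj1 at 185.6 CPM, against 166.7 and 75.73 and against 2.577 and 1.827 CPM in the other aged controls, although the GFP sort should leave out cells without Cre activity. Whether such cells came from inside the tumours was not tested, so an effect of age stays open.

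More genes were called for sgNupr1.2 than for sgNupr1.1 against the same young controls. GC content or length bias is argued against as the whole cause of the difference in counts, since with offsets sgNupr1.2 gave 339 genes and sgNupr1.1 gave 1, but only 217 were among the 530 called without offsets and lower calls went from 260 to 54, so it may account for part, as may library quality (54 genes and 1 with the percent of counts not aligned as a covariate). The ID prefix cannot be told apart from the guide: genes differing between the young guides (median 0.775 log2 CPM) had a signed median of -0.1518 in aged mice, where prefixes of targeted libraries do not differ, and 34 of 35 regroupings of those libraries were at least as high. Over 178 genes called without it, the lone AS library of sgNupr1.2 differed from young sgNupr1.1 by 0.661, above the 12 other AS libraries (-0.267 to 0.420) and below the 6 AT libraries (0.712 to 1.183), and 1 library excludes nothing. It stood at 0.999 over the 60 genes lower with sgNupr1.2 (AT 0.521 to 0.991). Over the 118 higher ones it stood at 0.446 (AT 0.692 to 1.484). Guide, prefix or quality may contribute, as this library had the highest percent not aligned (23.24). The other AS libraries include sgNupr1.1 ones used to choose the genes.

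Ribosomal protein and respiratory chain genes were lower in aged than in young targeted tumours. Young sgNupr1.2 libraries as the whole cause are argued against, since against young sgNupr1.1 alone the median was -0.3526 (SD over members 0.163, no single member called) and list means differed by -0.294 log2 CPM (exact permutation p = 0.00233), or -0.211 without replicate 6, the highest (exact p = 0.00884). GC content or length bias cannot be told apart from the groups: with offsets the median went from -0.529 (SD 0.212) to -0.3345 (SD 0.191), and as the fold changes shrank 22 of 48 called members kept their call. Library quality is a candidate source: with the percent of counts not aligned as a covariate the median was -0.1286 (SD 0.125) and none of the 48 kept its call, because the fold changes shrank while the median standard error went from 0.143 to 0.141. With that covariate 51 of 62 members were still negative, and an effect of age stays open and untested, since ID prefix follows age.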

How the results depend on the processing

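Tests with sex or the percent of counts not aligned as a covariate, with female mice alone, without the 3 libraries rich in macrophage or ciliated markers, with sex and without these libraries together and with GC content and length offsets were chosen after the results were seen, as was the contrast of the guides in young mice. Of 163 results for named genes 97 passed the threshold, and 144 kept their sign under all alternatives that omit no single library, while none was called under all of them. Across these alternatives 1764 named gene values kept their side of the threshold and sign, 546 lost the call, 45 gained it and 44 changed sign. For single gene lists 421 values kept call and direction, 236 lost the call and 25 turned. With single libraries omitted these were 4477, 374, 24 and 15 for named genes, and for lists 1754 kept call and direction, 100 lost the call and 6 turned. For each change below the cause was not tested. Simulated 2-fold changes were recovered at 56.7% for age in controls and targeting in aged mice and 92.5% for targeting in young mice. For age in controls, the cholesterol and AT1 lists were called under all 11 alternatives that omit no single library (adjusted p up to 0.0477 and 0.034).

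Numbers in brackets beside 0 are genes at an unadjusted p under 0.05, and the tool is edgeR unless named. With a stricter filter the count was 314 for age in controls. With limma voom the counts were 5 for age in controls, 3 for targeting in young mice, 4 for targeting in aged mice, 0 (1441) for the difference of effects and 0 (1449) for aged sgNupr1.1. They were 1 for aged sgNupr1.2 and 1627 for the guides in young mice. With edgeR on the groups of the contrast alone the counts were 2 for age in controls, 0 (1210) for targeting in young mice, 1 for targeting in aged mice, 0 (556) for young sgNupr1.1 and 186 for young sgNupr1.2. They were 0 (1322) for aged sgNupr1.1, 0 (1065) for aged sgNupr1.2 and 83 for the guides in young mice. With Xist as a covariate the counts were 1 for age in controls, 136 for targeting in aged mice, 0 (2047) for the difference of effects, 320 for young sgNupr1.2 and 4 for aged sgNupr1.1. With prefix AS or AH alone the counts were 5 for age in controls, 14 for targeting in young mice, 70 for targeting in aged mice, 519 for the difference of effects and 100 for the guides over both ages. They were 62 for aged sgNupr1.1, 0 (2130) for aged sgNupr1.2 and 1348 for the guides in young mice. Prefix AS leaves 1 young sgNupr1.2 library, so counts using it decide nothing. Among the aged libraries, prefix AH leaves out aged sgControl replicate 1 alone. With sex as a covariate the counts were 100 for age in controls, 94 for targeting in aged mice, 0 (2213) for the difference of effects and 5 for aged sgNupr1.1. With the percent of counts not aligned as a covariate the counts were 2 for targeting in young mice, 51 for targeting in aged mice, 2 for the difference of effects (neither among the 3), 36 for age in targeted tumours and 54 for young sgNupr1.2. They were 121 for aged sgNupr1.1, 2 for aged sgNupr1.2 and 151 for the guides in young mice. With female mice alone the counts were 0 (632) for age in controls, 0 (1731) for targeting in young mice, 0 (1405) for targeting in aged mice, 0 (2338) for the difference of effects and 949 for age in targeted tumours. They were 0 (696) for young sgNupr1.1, 0 (1961) for young sgNupr1.2, 0 (797) for aged sgNupr1.1, 0 (1088) for aged sgNupr1.2 and 0 (380) for the guides in young mice. Female mice leave 1 young sgNupr1.1 library, with the same limit. Without those 3 libraries the counts were 0 (1003) for age in controls, 0 (1721) for targeting in aged mice, 0 (2006) for the difference of effects, 0 (467) for young sgNupr1.1 and 6 for aged sgNupr1.1. They were 0 (1166) for aged sgNupr1.2 and 129 for the guides in young mice. Without them and with sex as a covariate the counts were 0 (859) for age in controls, 0 (1553) for targeting in aged mice, 0 (1692) for the difference of effects, 0 (497) for young sgNupr1.1 and 1 for aged sgNupr1.1. They were 0 (1003) for aged sgNupr1.2 and 136 for the guides in young mice. With DESeq2 the counts were 21 for targeting in young mice, 496 for targeting in aged mice, 332 for the difference of effects, 7 for the guides over both ages and 5 for young sgNupr1.1. They were 1474 for young sgNupr1.2, 363 for aged sgNupr1.1, 248 for aged sgNupr1.2 and 1110 for the guides in young mice. With a threshold of 0.1 the counts were 728 for targeting in aged mice, 183 for the difference of effects, 3446 for age in targeted tumours, 1642 for young sgNupr1.2 and 210 for aged sgNupr1.1. They were 20 for aged sgNupr1.2 and 1107 for the guides in young mice. With upper quartile normalization the count was 0 (2582) for the difference of effects. With no filter the counts were 0 (3023) for the difference of effects, 185 for young sgNupr1.2, 14 for aged sgNupr1.1 and 174 for the guides in young mice. With GC content and length offsets the counts were 0 (2050) for the difference of effects, 1413 for age in targeted tumours, 339 for young sgNupr1.2, 2 for aged sgNupr1.2 and 211 for the guides in young mice. With a 2-fold minimum the counts were 219 for age in targeted tumours, 100 for young sgNupr1.2 and 111 for the guides in young mice. Where genes were called, size factor or upper quartile normalization moved the share of higher calls by under 10 points. With DESeq2 it moved from 91.96 to 79.06% for age in controls, from 12.5 to 28.02% for targeting in aged mice, from 0 to 52.38% for targeting in young mice, from 100 to 34.94% for the difference of effects and from 75 to 37.1% for aged sgNupr1.2.

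Gene lists called by camera numbered 12 for age in controls, 3 and 15 for targeting in young and aged mice, 15 for the difference of effects, 7 for age in targeted tumours and 10 for the guides. Among these comparisons an estimated correlation left 2 for age in controls and 0 elsewhere, and fry called 2 for age in controls, 4 for age in targeted tumours and 0 elsewhere. Of the contrasts by guide and age, young sgNupr1.1 had 1 with an estimated correlation and the guides in young mice 3 with fry. With Xist or with sex as a covariate, 4 for age in targeted tumours were called. With the percent of counts not aligned as a covariate, 6 for targeting in young mice and 13 for age in targeted tumours were called. For female mice or prefix AS alone, list counts of contrasts with a group of 1 library are not given. Without those 3 libraries, 5 for targeting in young mice (also 5 with sex as a covariate) and 11 for age in targeted tumours were called. The covariance of age and targeting effects was -0.318 with the stricter filter.

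Lists that turned direction follow with adjusted p. For age in controls, cell cycle genes were on the higher side with prefix AS or AH alone (0.5345) and without the 3 libraries (0.921). Macrophage genes were higher among females (0.468) and with sex and without the 3 libraries (0.803), where club (0.977) and ciliated genes (0.0188) were lower. For targeting in aged mice, sex with the 3 libraries left out turned macrophage (0.508), club (0.2215) and ciliated genes (0.00156). Without the 3 libraries alone club genes stood at 0.543 and ciliated genes at 0.191, and with prefix AS or AH alone at 0.9275 and 0.263. For the difference of effects, females turned the high-plasticity (0.8765) and gastric lists (0.981), and offsets the ribosomal list (0.564). Club genes turned without the 3 libraries (0.679) and with sex as well (0.348), and ciliated genes likewise (0.405 and 0.0165). For the guides, females turned the unfolded protein list (0.903). The percent of counts not aligned turned the respiratory chain list for targeting in young (0.8212) and aged mice (0.01967) and for the difference of effects (0.01882), where it turned the ribosomal list too (8.713e-09).

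Named genes that turned sign follow with log2 fold changes. For age in controls with prefix AS or AH alone these were Cdhr4 -0.75, Cfap206 -1.135 and Ak7 -0.985. Without the 3 libraries they were Rsph4a -1.40, Cfap65 -1.05, Cdhr4 -2.51, Spag6l -0.65, Cfap206 -2.925, Cfap44 -0.21, Cdhr3 -0.84 and Ak7 -1.55. With sex as well they were Cyp2a5 -0.83, Rsph4a -2.185, Cfap65 -1.89, Cdhr4 -4.15, Spag6l -1.98, Cfap206 -4.18, Cfap44 -1.28, Cdhr3 -2.17, Ak7 -2.99, Dynlrb2 -0.41 and Rsph1 -0.82. For targeting in aged mice with prefix AS or AH alone they were AU040972 0.96, Mapk15 1.17, Ccdc40 0.35, Pcp4l1 1.002, Wnt11 0.54, Foxj1 1.05 and Dynlrb2 0.47. Without the 3 libraries they were AU040972 1.09, Mapk15 1.196, Ccdc40 0.40, Pcp4l1 1.055, Wnt11 0.71, Foxj1 1.11 and Dynlrb2 0.49. With sex as well they were AU040972 2.19, Mapk15 1.79, Ccdc40 1.205, Pcp4l1 1.64, Wnt11 1.06, Foxj1 1.73, Cfap126 0.12 and Dynlrb2 0.86.

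With single libraries left out, counts ran from 0 (1016, without aged sgControl replicate 1) to 961 (without aged sgControl replicate 2) for age in controls. For targeting in young mice they ran from 0 (1042, without young sgControl replicate 5) to 2 (without aged sgNupr1.1 replicate 4 or young sgControl replicates 6 or 7). For targeting in aged mice they ran from 3 (without aged sgControl replicate 1) to 834 (without replicate 2). For age in targeted tumours counts ran from 992 (without aged sgNupr1.2 replicate 3) to 2863 (without young sgNupr1.2 replicate 3). For the difference of effects they ran from 0 (2178 to 2711, in 19 omissions) to 264 (without aged sgControl replicate 3). For the guides over both ages all 30 omissions gave 0 in edgeR (944, DESeq2 7 and limma voom 0 with all libraries). Young sgNupr1.1 had 0 without its replicates 2 or 4 (382 and 414) and otherwise 1.

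Young sgNupr1.2 had 136 to 275 genes without young sgControl replicates 1, 3, 5, 6 or 7, 138 to 1805 without 1 of its own 7 replicates, and 830 without young sgNupr1.1 replicate 6. Aged sgNupr1.1 had 0 without its replicates 1, 3 or 4 (2144, 1681 and 1944) and 6, 446 and 105 without aged sgControl replicates 1, 2 and 3. It had 17 to 24 without aged sgNupr1.2 replicates 2 or 3, young sgNupr1.1 replicates 1, 2, 4 or 5, young sgControl replicates 1, 2, 3 or 6, or young sgNupr1.2 replicate 2. Aged sgNupr1.2 had 0 (1589), 205 and 149 without aged sgControl replicates 1, 2 and 3 and 7, 0 (1393) and 2 without its own replicates 1 to 3. The guides in young mice differed in 103 to 182 genes without young sgNupr1.1 replicates 1 to 5, 1455 without replicate 6, and 155 to 1175 without young sgNupr1.2 replicates 1, 2, 3, 5 or 6.

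The log2 fold change of Nupr1 with single libraries left out ran from -0.27 to 0.047 for age in controls. It ran from -1.23 to -0.97 and from -2.055 to -1.76 for targeting in young and aged mice, from -0.94 to -0.62 for the difference of effects and from -0.94 to -0.80 for age in targeted tumours. Called lists ran from 9 to 14 for age in controls, 2 to 5 for targeting in young mice, 8 to 16 for targeting in aged mice and 8 to 16 for the difference of effects (8 in both without aged sgControl replicate 3), 5 to 9 for age in targeted tumours and 8 to 14 for the guides. The covariance of age and targeting effects ran from -1.588 (without aged sgControl replicate 2) to -0.965 (without replicate 1), and was -1.501 without replicate 3.

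Among lists, omissions moved adjusted p from 9.997e-07 to 0.967 for cell cycle genes with age in controls, from 6.95e-04 to 0.83 for club and from 5.14e-12 to 0.254 for ciliated genes with targeting in aged mice. For the difference of effects they moved it from 1.79e-08 to 0.303 for ribosomal, from 0.00143 to 0.942 for club and from 4.66e-09 to 0.542 for ciliated genes. The highest of each came without aged sgControl replicate 1, except for ribosomal genes (replicate 2). Without aged sgControl replicate 1 the log2 fold changes with age were lowest, and without young sgControl replicate 7 highest: Rsph4a -1.39 and 8.54, Cfap65 -1.03 and 9.07, Cdhr4 -2.50 and 8.135, Spag6l -0.64 and 7.05, Cfap206 -2.915 and 7.77, Cfap44 -0.20 and 7.005, Cdhr3 -0.83 and 7.45, and Ak7 -1.54 and 6.39. For targeting in aged mice they were highest without aged sgControl replicate 1, with a range of -6.03 to 0.97 for AU040972, -4.73 to 1.17 for Mapk15, -5.11 to 0.36 for Ccdc40, -4.785 to 1.01 for Pcp4l1, -4.35 to 0.54 for Wnt11, -4.44 to 1.055 for Foxj1 and -3.21 to 0.47 for Dynlrb2.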

Other observations

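The tests of the guides against each other in young mice and of the percent of counts not aligned were chosen after the results were seen, and so were the lists and genes named here.

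By the preset test, cell cycle genes lay on opposite sides of the young controls with the 2 guides. With sgNupr1.1, 31 of 32 had positive values (median log2 fold change 0.47, adjusted p = 1.74e-14; adjusted p = 0.541 with an estimated correlation), and with sgNupr1.2 31 of 32 had negative values (median -0.58, adjusted p = 1.11e-05; adjusted p = 0.984 with an estimated correlation). The list mean was 4.24 to 4.76 log2 CPM in sgNupr1.1 libraries and 1.41 to 4.345 in sgNupr1.2 libraries, overlapping the controls, of which replicate 4 stood at 1.61 and the others at 3.485 to 4.61. In aged mice both guides had higher cell cycle genes, by medians of 0.57 and 0.68 (adjusted p = 1.17e-06 and 1.95e-07; adjusted p = 0.605 and 0.5995 with an estimated correlation). No single member was called in these 4 contrasts, over all genes or adjusted over the list alone. NF-kappaB and acute-phase genes were lower with sgNupr1.1 in young mice (median -0.38, adjusted p = 1.75e-13), and this list passed with an estimated correlation (adjusted p = 0.00997) but not with fry (adjusted p = 0.0933). Of its 26 members 22 had negative values, 0 were called over all genes and 2 adjusted over the list alone. Between the young guides the list differed as well (median -0.44, adjusted p = 2.95e-04; adjusted p = 0.527 with an estimated correlation), and the serum amyloid gene Saa3 was lower with sgNupr1.1 (-1.79, SE 0.47, adjusted p = 0.0431; 7 adjusted over the list alone). DNA methylation genes were higher with sgNupr1.1 (median 0.53, adjusted p = 1.46e-04; adjusted p = 0.527 with an estimated correlation), with the maintenance methyltransferase gene Dnmt1 at 0.58 (SE 0.12, adjusted p = 0.00906) as the 1 of 10 that passed over all genes (6 adjusted over the list alone).

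Iron handling genes did not pass the preset list test with age in targeted tumours (31 genes, median 0.14, adjusted p = 0.237), while fry gave an adjusted p of 0.0457. The exporter Slc40a1, the reductase Cybrd1 (adjusted p = 0.013), the importer Slc39a14 (0.67, SE 0.19, adjusted p = 0.0227) and the ferroxidase Heph (2.995, SE 0.91, adjusted p = 0.0274) rose as the 4 called members (5 adjusted over the list alone). With the percent of counts not aligned as a covariate these 4 calls ended, at 0.83 for Slc40a1, 1.27 for Cybrd1, 0.48 for Slc39a14 and 1.44 for Heph (adjusted p = 0.239, 0.226, 0.477 and 0.741). With age in controls and with targeting in young and aged mice the list was at adjusted p = 0.756, 0.381 and 0.793.

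Some genes that set the young sgNupr1.2 libraries apart were also high in 1 aged library of the other guide. Ier5l was at 9.36 to 52.0 CPM in the 6 AT libraries, 2.53 CPM in the AS library of sgNupr1.2 and 20.7 CPM in aged sgNupr1.1 replicate 4. Cul3 was at 30.6 to 98.9, 28.3 and 81.1 CPM in these, and Ppp2cb at 65.4 to 145 CPM, 43.7 CPM and 124 CPM. Rbl1 was at 7.92 to 13.7, 9.78 and 19.9 CPM there. Young sgControl replicate 4 (prefix AS) had 9.57 CPM, so low Rbl1 was not particular to sgNupr1.2.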
